A study of Mus musculus with 3 samples.

How the data were processed

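Genomic DNA of SFME cells was compared with control mouse DNA on 3 NimbleGen arrays of 2 colours, SFME DNA in Cy3 and control DNA in Cy5. This assignment follows the source names; the cell type entry names SFME cells for both channels, and the source name was taken as right for Cy5. The groups were sphere cells, cells differentiated for 24 h with TGFB and cells differentiated for 12 h with 10% FCS, with 1 array each; the groups and times are in the sample titles, and the differentiation and the 10% in the source names. The direction of every ratio, SFME over control, rests on this assignment.

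The authors deposited 1 table per array with 713358 probes. Per the file headers it holds the log2 signals of both channels, an uncorrected log2 ratio, a log2 ratio after spatial correction, a log2 ratio after a further normalization between channels, and the G+C of each probe as a fraction. The deposited series table holds the normalized log2 ratios again, equal to those of the array tables for all 713358 probes; its column medians were 0.002, 0.015 and 0.004. The software and the methods of the corrections are not given in the sources used here, nor is the genome build. Signals reached the ceiling of the scale in both channels for 0 probes on the sphere array, for 71 (Cy3) and 89 (Cy5) on the TGFB array and for 1 in each channel on the FCS array.

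The spatially corrected ratio was used, centred on the autosomal median of each array (-0.015, -0.02 and -0.022 before centring), with no further normalization, because many probes of a copy number array may truly shift one way. Chromosome medians of all 3 kinds of ratio had been looked at when this choice was stated. Differences between arrays were taken per probe and centred again. Probes were grouped in windows of 100 kb with at least 5 probes (24010 autosomal windows, median 28 probes), and a region is a run of at least 3 adjacent windows with medians at or above 0.25 or at or below -0.25. A window with too few probes ends a run. Errors of region medians are standard errors from the spread of the region's probes. For chromosomes the SD of 1 Mb bin medians and a 95% bootstrap interval over bins (1000 draws) were computed. With 1 array per group no test between groups was made, and the number of arrays limits the precision.

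The region rule was tested on simulated data made from shuffled probes of the sphere array over 24010 autosomal windows. It recovered 9 of 50 regions shifted by 0.25 and 50 of 50 shifted by 0.4, 0.6 or 1, with 0 false regions. A region counted as recovered where over 50% of its length was called. Full recovery at 0.4 and above holds for the simulated regions and not for every segment of the arrays. The rule missed the chromosome 4 segment from 88934138 to 89214353 on the sphere and TGFB arrays, where its medians were -2.48 and -2.34. A least-squares segmentation with a minimum of 10 probes recovered 24 of 50 at 0.25 and 50 of 50 above, with 9 false regions, and gave 10 regions where no shift had been put in. Shuffling removes any structure along the genome, such as a trend with G+C, so these counts describe noise independent between probes alone.

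By a rule written before the data were examined, the named regions are, per array and per difference, the 10 of largest absolute median in each direction, and X, Y and any autosome at or beyond 0.1 are always given. Their restriction to autosomes, the deepest losses, and the blocks of chromosomes 11 and 14 were chosen after the data were seen. Block limits came from a least-squares fit of 1 interval to window medians of the spatially corrected values. On chromosome 14 such a free interval took a part ahead of the reported block after TGFB (8.1 to 50.5 Mb) and a middle part after FCS (54.4 to 81 Mb). The fit was therefore repeated with the interval held to run to the chromosome end, a change made after the first result was seen. Limits were first taken from values corrected for G+C, with which the starts on chromosome 14 lie close together; the reported limits are those of the spatially corrected values.

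Alternatives fixed before the data were examined were windows of 50 and 200 kb, thresholds of 0.15 and 0.35, runs of at least 2 windows, means in place of medians, no centring, centring on the mode, subtraction of a running median over 5 Mb, segmentation, and the deposited series table; for the agreement of arrays they were 1 Mb windows, autosomes alone and windows outside called regions. The uncorrected ratio, a correction for G+C (a quadratic in the G+C of the window and of its 1 Mb) and all alternatives for the blocks were added after the data had been seen. The 9 gene lists fixed beforehand were not run and no region is given gene names, because the annotation at hand belongs to another genome build. Segment means of the authors were not used here. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.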

Results

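Copy number along the genome was measured in SFME cells, a mouse embryo cell line grown without serum, by comparative genomic hybridisation on 2-colour tiling arrays. On each array, DNA of SFME cells labelled with Cy3 was hybridised together with control mouse genomic DNA labelled with Cy5. The 3 arrays held sphere cells, cells differentiated for 24 h with TGFB (transforming growth factor beta, a signalling protein) and cells differentiated for 12 h with 10% FCS, with 1 array per group. No group had a replicate, so no difference between arrays could be set against a spread between cultures, no p-value is given, and every error below describes the probes of an array only. Each array carried 713358 probes with a median spacing of 3537 bp. Median Cy3 and Cy5 signals were 5595 and 4285 for sphere, 10470 and 7665 for TGFB, and 4708 and 4099 for FCS. The probe-to-probe noise (SD of the log2 ratio) was 0.22, 0.26 and 0.18 in the same order. Positions are those of the array files, whose chromosome 1 is 197195432 bp long. The genome build and the methods of the deposited corrections are not given in the sources used here.

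At the level of whole chromosomes, X was higher and Y lower in SFME DNA than in control DNA on all 3 arrays, and the autosomes stayed close to 0. The X median was 0.60 in sphere cells, 0.58 after TGFB and 0.54 after FCS, with an SD of 1 Mb bins of 0.17, 0.19 and 0.15 over 164 bins. Y probes had medians of -1.64, -1.56 and -0.98 (SD of bins 0.23, 0.26 and 0.16, 688 probes), and the unplaced Y sequence (Y_random, 5719 probes) had medians of -2.78, -2.77 and -2.19. Chromosome 11 after TGFB, at 0.10 (SD of bins 0.17), was the only autosome at or beyond 0.1 on any array. Its medians in sphere and FCS cells were 0.05 and 0.06 (SD of bins 0.08 and 0.09). Chromosome 14 was the lowest autosome after TGFB, at -0.096, and after FCS, at -0.07 (SD of bins 0.16 and 0.12). The deposited between-channel normalization moved the X median to 0.53 after TGFB and 0.50 after FCS.

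**Figure D1:**
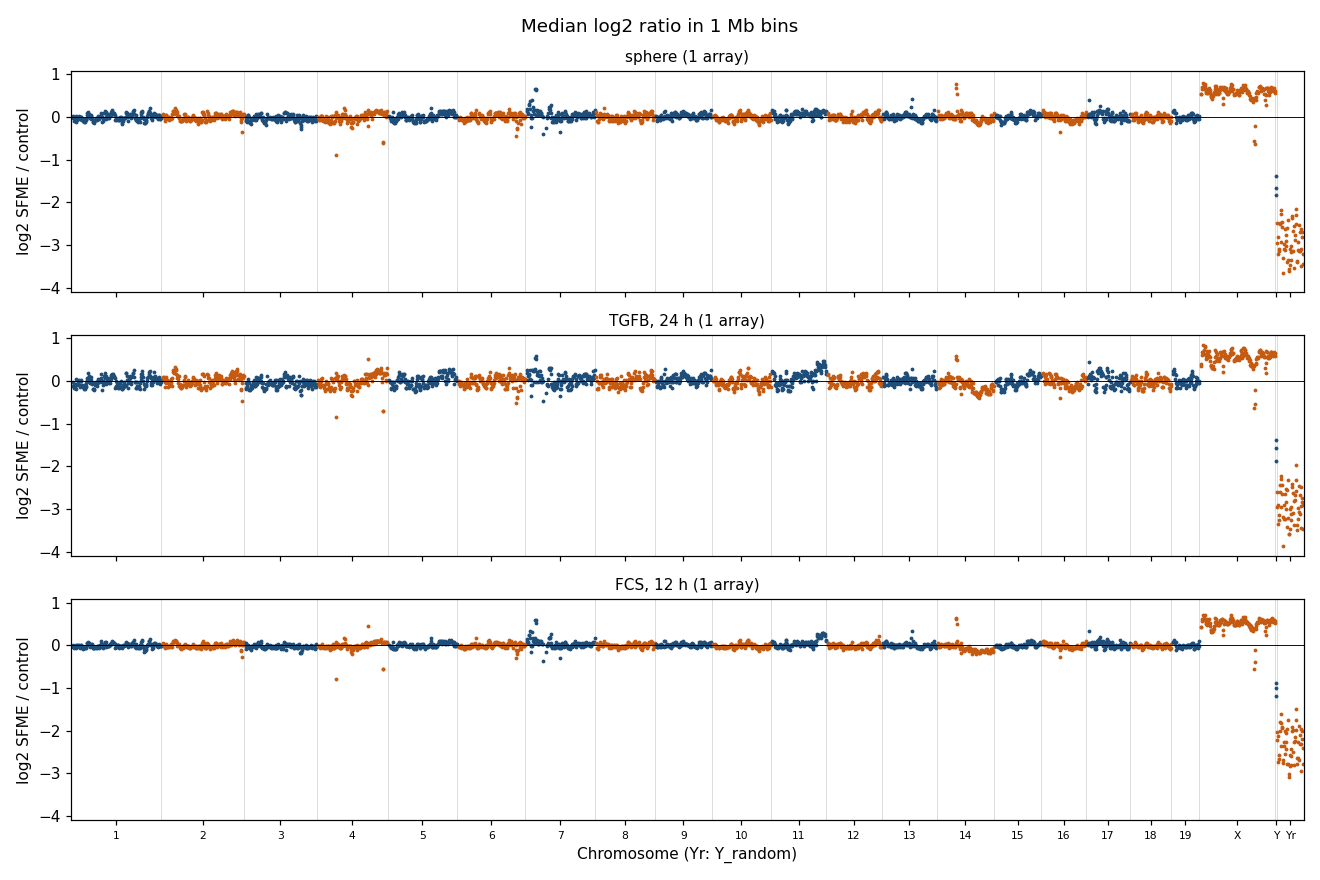
Median log2 ratio of SFME over control DNA (vertical axis) in 1 Mb bins along all chromosomes (horizontal axis), 1 panel per array and 1 point per bin, colours alternating by chromosome. X lies near 0.60, 0.58 and 0.54 in sphere, TGFB and FCS cells, and the Y points are less negative on the FCS array (median -0.98) than on the sphere array (-1.64).

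A set of segments was higher or lower in SFME than in control DNA on all 3 arrays. The sex and strain of the cells and of the control DNA are not given in the labels, so these segments are differences between both DNAs and are not assigned to either. For X and Y, SFME DNA held more X and much less Y sequence than control DNA relative to the autosomes. The sex chromosomes of both DNAs thus do not match, and the cause was not tested. Among the highest were chromosome 7 from 54900001 to 55200000, at 0.92 ± 0.10 in sphere, 1.20 ± 0.11 in TGFB and 0.86 ± 0.08 in FCS cells (SE of the median over 86 probes), and chromosome 14 from 44700001 to 45400000, at 0.91 ± 0.05, 0.85 ± 0.06 and 0.79 ± 0.04 (177 probes). The neighbouring stretch of chromosome 14 from 42000001 to 44600000 stood at 0.65, 0.51 and 0.59 (SE 0.02 on each array, 654 probes). Chromosome 7 from 21100001 to 24100000 stood at 0.66, 0.57 and 0.58, and chromosome 17 from 6200001 to 6900000 at 0.50, 0.57 and 0.47 (0.34, 0.30 and 0.35 after correction for G+C). Lower segments in common included chromosome 4 from 41700001 to 42900000, at -1.06 ± 0.06, -0.97 ± 0.06 and -0.97 ± 0.06 (252 probes), chromosome 7 from 74800001 to 75500000, at -0.63, -0.64 and -0.58, and chromosome 4 from 145000001 to 147200000, at -0.57, -0.66 and -0.54. Their median control signals were high, at percentiles 95.9, 92 and 95.2, then 84.5, 79.6 and 82.8, then 97.9, 95.4 and 95.9 of all probes. How such bright probes bear on these ratios was not examined.

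The lowest values lay in segments of 91.8 to 301 kb, whose limits were taken from a segmentation of the sphere array after the values had been seen. Chromosome 16 from 41008585 to 41309769 (84 probes) had medians of -2.78 ± 0.11 in sphere, -2.67 ± 0.13 in TGFB and -2.12 ± 0.11 in FCS cells. Chromosome 4 from 88934138 to 89214353 (68 probes) had medians of -2.48 ± 0.14, -2.34 ± 0.17 and -2.08 ± 0.14. In the called windows of both, the median SFME signal lay at percentiles 0.418 to 1.02 of all probes. Background was not measured, so how far it limits these depths is not known. That segment passed the region rule on the FCS array alone, where a partly covered window at its edge reached the threshold, although it was as deep on the other arrays. Segments on chromosome 2 from 77711537 to 77861106 (42 probes; -1.63, -1.68 and -1.56), chromosome 6 from 129957924 to 130085482 (37 probes; -1.61, -1.60 and -1.03) and chromosome 19 from 9227748 to 9319546 (25 probes; -1.75, -1.71 and -1.25) completed the set.

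By the region rule (at least 3 adjacent 100 kb windows at or beyond 0.25), the autosomes held 21 higher and 21 lower regions in sphere cells, 118 and 83 after TGFB, and 31 and 15 after FCS. With X, Y and Y_random included the counts were 38 and 62, 139 and 126, and 50 and 56. The restriction to autosomes was chosen after the data were seen, because calls on X and Y are pieces of whole-chromosome differences. Shuffling the probes over autosomal positions gave 0 regions on every array, which describes noise independent between probes alone. Of the sphere regions, 13 of 21 higher and 15 of 21 lower ones shared a window with calls on both other arrays. Of the TGFB regions, 95 of 118 higher and 66 of 83 lower ones shared a window with neither. Part of the excess on the TGFB array went with the base composition of the windows. Its log2 ratio had a correlation with window G+C of 0.56 across windows, against 0.41 for sphere and 0.32 for FCS. A correction for G+C left 42 and 43 regions, against 19 and 18 for sphere and 21 and 15 for FCS. Part of the excess thus remained. Before that correction, chromosome 11 held 18 of the 118 higher TGFB regions, against 0 for sphere and 12 for FCS. Chromosome 14 held 28 of the 83 lower ones, against 1 for sphere and 1 for FCS. The split of TGFB calls also moved with the zero point, to 71 higher and 95 lower without centring and to 165 and 57 with centring on the mode.

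**Figure D2:**
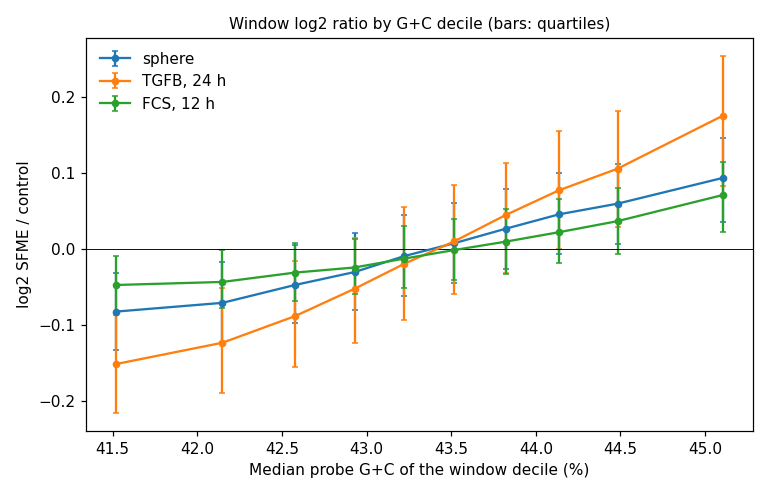
Median log2 ratio of 100 kb autosomal windows (vertical axis) by decile of window G+C (horizontal axis, median probe G+C in percent), 1 line per array, bars spanning the quartiles of the windows. From the lowest to the highest decile the median goes from -0.15 to 0.18 on the TGFB array, from -0.08 to 0.09 on the sphere array and from -0.05 to 0.07 on the FCS array.

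The series sets sphere cells against cells differentiated with TGFB. After TGFB a long distal part of chromosome 11 was higher than in sphere cells. No lower autosomal region of the difference passed, but a threshold of 0.15 gave 34 higher and 50 lower ones. Of the 16 higher autosomal regions at the reported threshold, 13 lay in that part of chromosome 11. The highest of these 13 were chromosome 11 from 115500001 to 116300000, at 0.32 ± 0.02 (227 probes), from 116700001 to 118400000, at 0.31 ± 0.01 (480 probes), and from 109200001 to 109600000, at 0.31 ± 0.03 (114 probes). A least-squares fit of 1 interval, made after this was seen, placed the block from 101400001 to 120200000, with a median difference of 0.26 and all 188 windows above 0. Medians of 1861 overlapping stretches of that length on autosomes other than 11 and 14 lay between -0.06 and 0.09. Here and below, stretches elsewhere leave out both chromosome 11 and chromosome 14, so the range for either block does not hold the other block. The blocks were also placed by a fit and the stretches were not, so these ranges do not allow for that choice. Chromosome 14 was lower after TGFB from 50500001 to its end, by a median of -0.14, with 16 of 747 windows above 0 and stretches elsewhere between -0.03 and 0.04. Neither block had been named before the data were examined. After correction for G+C the chromosome 11 difference was 0.22 and the chromosome 14 difference -0.12. The 3 chromosome 11 regions above then stood at 0.24 ± 0.02, 0.22 ± 0.01 and 0.27 ± 0.03, and 10 of the 13 had medians below the threshold of 0.25; in all, 6 higher autosomal regions and 1 lower one passed.

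The other 3 regions of this difference lay on chromosome 4, from 111700001 to 112300000 (0.48 ± 0.04, 164 probes), from 112500001 to 113100000 (0.36 ± 0.04, 159 probes) and from 121600001 to 121900000 (0.30 ± 0.04, 80 probes). Their probes were among the dimmest of the array in both channels: the median control signal in sphere cells lay at percentiles 0.097, 0.23 and 0.388 of all probes. With the normalized values the 3 differences became 0.12, 0.00 and -0.02.

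Sphere cells were also set against cells differentiated with FCS. The same distal part of chromosome 11 was higher after FCS, by a smaller amount that did not reach the region threshold. The interval fitted in this difference ran from 101500001 to 119800000, with a median of 0.14 and all 183 windows above 0, against -0.04 to 0.05 for equal stretches elsewhere. Y probes were higher after FCS by 0.54 and Y_random probes by 0.52, and X was lower, at -0.07. Of 41 higher regions 37 lay on Y and Y_random together. The 4 autosomal ones were chromosome 16 from 41000001 to 41300000 (0.64 ± 0.05, 83 probes), chromosome 6 from 129900001 to 130200000 (0.38 ± 0.05, 85 probes), and chromosome 4 from 121600001 to 121900000 (0.34 ± 0.04) and from 113000001 to 113300000 (0.29 ± 0.04). The chromosome 16 and chromosome 6 regions are below 0 on every array and were less so after FCS, and the chromosome 4 regions lie on the dim probes described above. With the normalized values these 4 differences became 0.40, 0.25, 0.05 and 0.02 in the same order, and 1 higher autosomal region passed.

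Chromosome 14 was lower after FCS too, but where the lower part began was not settled. Fitted to the end of the chromosome, it started at 42000001 with the spatially corrected and the uncorrected values, at 50700001 with the normalized values and at 51400001 after correction for G+C. The median difference from 42000001 on was -0.08, with 114 of 832 windows above 0 and equal stretches elsewhere between -0.01 and 0.02. The start at 42000001 coincides with that of the higher region of chromosome 14 given above, which was itself lower than in sphere cells after FCS (-0.12 ± 0.01) and after TGFB (-0.14 ± 0.01).

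**Figure D3:**
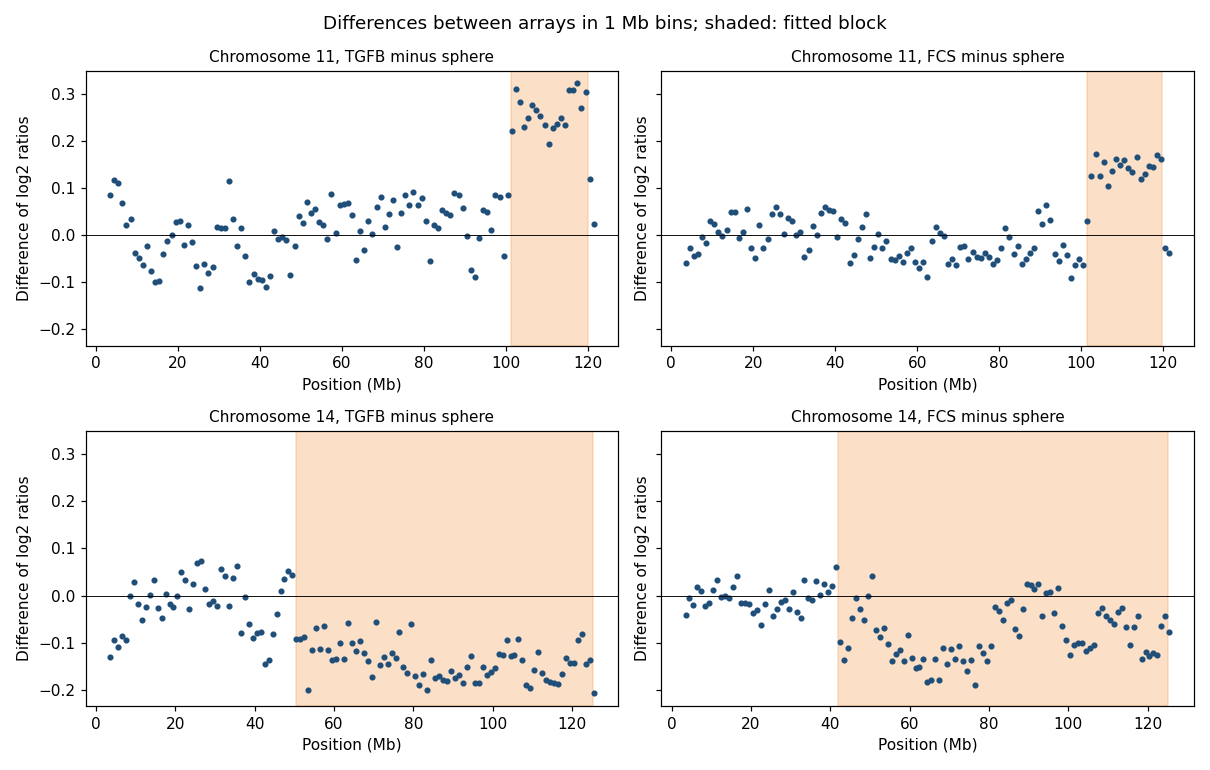
Difference of log2 ratios from the sphere array (vertical axis) in 1 Mb bins along chromosomes 11 and 14 (horizontal axis, Mb), TGFB on the left and FCS on the right, 1 point per bin, shading for the interval fitted to that difference. On chromosome 11 the shaded bins rise above the rest in both columns (medians 0.26 and 0.14), and on chromosome 14 the shading begins at different places (50.5 and 42 Mb).

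The comparisons with sphere cells share 1 array, so their values are not independent. Of 96 windows in higher regions of the TGFB difference and 12 of the FCS difference, 4 were shared, against 0.048 for independent lists of these sizes among 24010 windows. All 4 lay on the dim probes of chromosome 4 described above. Across autosomal windows the 2 differences had a correlation of 0.0327 and a covariance of 0.000181. With the probes of each array shuffled separately and the same shared array, the values were 0.335 and 0.00224. Such shuffling also removes the profile common to the arrays, so these values do not measure what the shared array adds. Because both differences subtract the same array, an overlap does not count as a repeat on separate arrays.

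Between the TGFB and FCS cells, which differed in treatment and time together, few regions passed the rule. FCS was higher in 4 autosomal regions, chromosome 16 from 41000001 to 41300000 (0.50 ± 0.07) and chromosome 6 from 131700001 to 132000000 (0.40 ± 0.06), from 129900001 to 130200000 (0.37 ± 0.05) and from 132900001 to 133200000 (0.28 ± 0.05). All 4 were below 0 on each array. FCS was lower in 1 region, chromosome 6 from 114300001 to 114600000 (-0.31 ± 0.04, 66 probes), a value of -0.19 after correction for G+C. With Y and Y_random included, 44 regions were higher, 40 of them on these 2 sequences together. Centring on the mode gave 4 higher and 2 lower autosomal regions, and a threshold of 0.15 gave 118 and 120.

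No array ran in the opposite direction to another as a whole, and all 3 profiles were correlated. Each ratio was taken against control DNA and rose with G+C, and how much of the correlation this gives was not tested. Pearson correlations of window medians, which describe windows and not replicates, were 0.974 for TGFB and sphere, 0.98 for FCS and sphere, and 0.964 for FCS and TGFB, with Spearman values of 0.855, 0.781 and 0.789. On autosomes alone the Pearson values were 0.846, 0.827 and 0.799, since X and Y carry much of the range.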

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

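The uncorrected ratio, the correction for G+C and all alternatives for the chromosome 11 and 14 blocks were chosen after seeing the data; the rest were fixed before. Counts below are autosomal, higher then lower, in the order sphere, TGFB and FCS, then the differences TGFB minus sphere, FCS minus sphere and FCS minus TGFB. The reported counts were 21 and 21, 118 and 83, 31 and 15, then 16 and 0, 4 and 0, and 4 and 1. They depended strongly on the rule. Windows of 50 kb gave 57 and 45, 277 and 176, 75 and 30, then 36 and 2, 9 and 1, and 11 and 9. Windows of 200 kb gave 8 and 12, 51 and 29, 16 and 6, then 5 and 0, 0 and 0, and 0 and 0. A threshold of 0.15 gave 126 and 96, 407 and 410, 52 and 57, then 34 and 50, 18 and 13, and 118 and 120. A threshold of 0.35 gave 16 and 13, 27 and 28, 14 and 11, then 3 and 0, 1 and 0, and 1 and 0. Runs of at least 2 windows gave 42 and 44, 240 and 162, 53 and 28, then 23 and 1, 8 and 0, and 12 and 4. Segmentation, which also called 10 regions on simulated data without any shift, gave 151 and 250, 178 and 214, 228 and 285, then 15 and 3, 31 and 8, and 16 and 11; it takes segments from 10 probes on, and a window had a median of 28. Subtracting a running median over 5 Mb gave 14 and 13, 18 and 29, 13 and 12, then 2 and 0, 2 and 0, and 1 and 0. Correction for G+C gave 19 and 18, 42 and 43, and 21 and 15, then 6 and 1 for TGFB minus sphere and 2 higher for FCS minus sphere. Means of probes gave 36 lower for sphere and 24 lower for FCS. Without centring TGFB had 71 higher and 95 lower regions, and with centring on the mode 165 and 57, with 2 lower for FCS minus TGFB. The normalized values of the series table gave 1 lower for TGFB minus sphere and 1 higher for FCS minus sphere, and the uncorrected ratio 2 lower for FCS minus TGFB. Apart from window, threshold, run length and segmentation, whose construction changes what can be called, the cause was not tested. TGFB had more higher regions than sphere under all 13 alternatives and more lower ones under 12, but under segmentation it had fewer lower ones than sphere (214 against 250) and fewer of both kinds than FCS (178 and 214 against 228 and 285).

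The signs of the X, Y and Y_random medians were kept under all alternatives run. The X median with means of probes was 0.57, 0.55 and 0.51 for sphere, TGFB and FCS, with normalized values 0.53 for TGFB and 0.50 for FCS, and without centring 0.52 for FCS. The Y_random median of sphere, -2.78 as reported, was -2.565 with normalized values. Correlations for TGFB and sphere, FCS and sphere, and FCS and TGFB were, as Pearson values, 0.991, 0.994 and 0.987 in 1 Mb windows, 0.846, 0.827 and 0.799 on autosomes alone, and 0.921, 0.928 and 0.887 outside called regions. The Spearman values were 0.947, 0.914 and 0.8998, then 0.817, 0.721 and 0.732, then 0.797, 0.712 and 0.698.

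The chromosome 11 block kept its sign. Its median went from 0.26 to 0.22 for TGFB and from 0.14 to 0.17 for FCS after correction for G+C, and to 0.16 for FCS with normalized values; the cause was not tested. The chromosome 14 block of TGFB went from -0.14 to -0.12 after correction for G+C and to -0.13 within the limits fitted for FCS, which start at 42 Mb; the cause was not tested. Subtracting the running median over 5 Mb removes by construction any block longer than its span, and left 0.009 and 0.009 on chromosome 11 and -0.001 and -0.0025 on chromosome 14. The 79 named regions are counted per array or difference, so the same or an overlapping stretch can count more than 1 time. Among their 553 values under alternatives, 468 stayed within the half-width of the 95% interval of the reported value. A further 84 moved beyond it and 1 changed sign. The latter was chromosome 4 from 121600001 to 121900000, TGFB minus sphere, on probes near the lowest signal. It had 0.30 with the reported and -0.0195 with the normalized values, and the cause was not tested. Background was not measured, so how far signal over background limits the values is not known; it bears on the chromosome 4 regions between 111700001 and 121900000, dim in both channels, and on chromosome 16 from 41000001 and chromosome 4 from 88900001, dim in SFME signal. No paired analysis was possible because each group had 1 array. The gene lists and segment means of the authors were not run.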

Other observations

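The tests of the TGFB regions against G+C, of the blocks against the scale of the ratios and against the deposited corrections, and of the FCS array against a constant background and against admixed DNA by Y_random, chromosome 4 and X were stated before their results were seen; all other tests here were chosen afterwards. The X chromosome was not even along its length. Its bin from 120000001 to 125000000 had medians of 0.09, 0.04 and 0.13 in sphere, TGFB and FCS cells (1133 probes), against 0.57, 0.55 and 0.53 in the next bin. Regions of chromosome 4 between 111700001 and 113300000 were dim in both channels, at percentiles 0.097 to 0.817 of control signal and 0.148 to 0.346 of SFME signal on the sphere array, so a ratio there compares 2 signals near the lowest on the array.

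For the distal block of chromosome 11, higher in both differentiated samples than in sphere cells, dependence on G+C as the whole cause is argued against by medians of 0.22 (TGFB) and 0.17 (FCS) after its removal, where equal stretches elsewhere reached 0.04 and 0.03; a different scale of ratios by residual medians of 0.26 and 0.18, against at most 0.08 and 0.05 elsewhere; and the deposited corrections by uncorrected medians at 102% and 100% of the corrected ones. The limits fitted in both differences lay at most 0.4 Mb apart (95% of refits 0.2 to 0.7), but both subtract the same sphere array, so this decides nothing about a copy number difference carried by part of the cells. Fitted on the TGFB and FCS arrays against control with spatially corrected values, the starts lay 94.7 Mb apart, past the 5 Mb bound. There the TGFB fit took 6.7 to 100.1 Mb, a part outside the block, and the FCS fit 101.4 to 119.9 Mb, the block itself. That distance sets unlike limits against each other, so it decides nothing. After correction for G+C the limits lay at most 0.2 Mb apart. Requiring both kinds of values was decided after they were seen to part, and this hypothesis stays open. A feature of the shared sphere array alone is argued against by the block's own level against control DNA after correction for G+C, 0.25 on the TGFB and 0.20 on the FCS array, where equal stretches elsewhere reached 0.15 and 0.12. Whether treatment or the history of separate cultures accounts for it cannot be told apart with 1 array per group.

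On chromosome 14 the same tests gave -0.125 and -0.0909 after correction for G+C, residuals of -0.130 and -0.0894, levels against control DNA of -0.135 and -0.098 on the TGFB and FCS arrays, and uncorrected medians at 98.6% and 100% of the corrected ones, all outside the range of equal stretches elsewhere or above the stated bound. In the differences the fitted starts lay 8.5 Mb apart, past the 5 Mb bound, with refits from 2.45 to 12.5 Mb (the use of the spread was decided after the distance was seen), and within 1 Mb with normalized values or after correction for G+C. On the arrays against control they lay 26.3 Mb apart with spatially corrected values and 0.8 Mb (0.295 to 6.93) after correction for G+C, so a shared copy number difference may or may not underlie this block. With 1 array per group, treatment and culture history cannot be told apart here either.

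Most TGFB regions were called on no other array. Outside chromosomes 11 and 14, the windows of the 82 higher regions of this kind had a median G+C percentile of 94.5 and those of the 36 lower ones 12.6, which is what a dependence of the ratios on G+C would give. Noise independent between probes is argued against by 0 regions after shuffling. Noise shared by neighbouring probes is removed by shuffling and was not tested. G+C also goes with the time of replication in S phase, so a larger share of replicating cells may give the same pattern; no timing data were used here and this was not tested.

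Y and Y_random probes and some of the lowest autosomal segments were less negative on the FCS array; the chromosome 2 segment was not beyond its error (-1.63 in sphere, -1.56 in FCS cells). For a constant background in Cy3, the FCS minus sphere value differed by 0.005 (-0.02 to 0.03) between dim and bright probes of Y and Y_random together (2136 each). This met the condition set against it, but the probes were split by control signal. Whether their SFME signal rose with control signal was not examined, so this test cannot decide. A lower scale of all ratios is argued against by X, whose FCS to sphere ratio (0.894) exceeded that of Y by 0.294. The X ratio also lay above that of Y_random (0.785) and of the chromosome 6 (0.639) and 16 (0.765) segments. The intervals of the chromosome 2, 4 and 19 segments hold the X ratio. Regions higher in sphere cells had a ratio of 0.880 (0.855 to 0.899), near that of X. Over all autosomal windows, however, the slope of the FCS on the sphere array was 0.658, against 1.17 for TGFB. This slope is nearer to the ratio of Y (0.6) and goes with a narrower autosomal profile after FCS. How far probe noise and G+C bear on the slope was not examined. Admixed DNA with a Y chromosome would need 1 share. The shares were worked out for admixed DNA equal to the control DNA and for ratios linear in the amount of DNA. Neither assumption was tested. The shares from Y_random (0.0873), the chromosome 4 segment (0.0697) and X (0.127) ranged over 0.0575. This range met neither the condition set for admixture nor the condition set against it. On these assumptions, a single share behind all of these differences is argued against by Y, at 0.272 and higher than Y_random by 0.185. The chromosome 6 segment, at 0.241 (0.178 to 0.282), argues against it on the same assumptions. The intervals of chromosomes 2 (0.0225), 4, 16 (0.0977) and 19 (0.173) hold the Y_random share and decide nothing. The FCS minus sphere log2 differences themselves were alike on Y and Y_random (0.54 and 0.52). If either assumption fails, unlike shares decide nothing. A smaller admixture together with another effect may remain, and no biological explanation was tested.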
